A study of Mus musculus with 9 samples.

How the data were processed

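RNA of sorted CD4+ GFP+ regulatory T cells was hybridised to Affymetrix Mouse Gene 2.1 ST arrays, 1 array per sample, from 225 ng of total RNA per the labels' protocols. The groups, taken from the sample titles, were control lung (uninjured), resolving lung and resolving spleen (lipopolysaccharide at 3 mg/kg), with 3 arrays each. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical in part. Harvest days, the number of mice per array and scan batches were not given in the sources used here.

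The values used were log2 expression values as deposited, 1 column per array and 31351 rows. Per the submitters' processing notes, Affymetrix Expression Console, RMA (which corrects background, normalises between arrays and summarises probes) and Partek were used, with versions and order not given in the sources used here. That the scale is log2 was read from the values, which lay between 1.07 and 12.86 in all 9 columns. RMA makes the distributions of the arrays alike, so a change shared by most genes would be removed, and it compresses the changes of dim genes.

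Rows named by RefSeq, Ensembl transcript or GenBank accessions were given gene symbols from an NCBI RefSeq gene list (assembly GRCm38.p6), used for names alone, since no build was given for the deposited rows. Of the rows, 21057 matched 1 symbol, 0 matched several and 10294 (32.8%) stayed unnamed here and out of the tests of named genes. For the 34 genes with several rows, the row with the highest mean stood for the gene (0 of them had rows that changed in opposite directions), which left 21023 genes. No gene was removed for low signal. The dim level was taken as the 95th percentile of 915 olfactory receptor genes, which lay between 3.32 and 3.52 per array. Where a named gene lay at or below it in every array of 1 group, the difference printed is the mean of the brighter group minus the mean dim level of the other group's arrays, as a lower limit. This rule was chosen after the data were examined, and the adjusted p is that of the fit.

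All 9 arrays were fitted in 1 linear model with limma 3.58.1 (lmFit and eBayes, no trend, no block; R 4.3.3, statmod 1.5.0, data.table version 1.17.8), with 6 residual and 2.29 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum, two-sided. An exact permutation test of 3 against 3 arrays cannot go below a p of 0.1 and was not used. All 3 pairs of groups were compared, and genes past both tests of resolving lung in the same direction were counted. That count was set against the overlap of independent lists and against 50 simulated data sets with no change. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 tested lists of each comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way and compares them with no other genes, were run as alternatives. Called lists are described as shifted. Splits of the arrays that mixed the groups called 4 to 19 lists too. So a call at the preset correlation does not by itself show a difference between the groups.

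The 31 lists held 730 genes, of which 636 were measured. They covered the T cell identity, Treg core, effector Treg activation, resting or lymphoid Treg, tissue Treg and repair, growth factor and matrix, chemokine, chemokine and homing receptor, helper T cell lineage, cell cycle, interferon-stimulated, NF-kB, immediate early and dissociation, heat shock, glycolysis, cholesterol synthesis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein and sex-linked genes. They also covered markers of macrophages, neutrophils, dendritic cells, B cells, CD8 T or NK cells, conventional CD4 T cells, epithelium, endothelium, fibroblasts and smooth muscle, erythroid cells and platelets, and mast cells and basophils. The mitochondrially encoded list, with 2 of 26 members measured, was below the minimum of 3 and was not tested. Markers of other cells were not all silent in these samples: 8 of 25 measured macrophage, 5 of 21 epithelial, 11 of 18 B cell and 10 of 13 conventional CD4 T cell genes lay above the dim level in all 9 arrays, and 8 of the last 13 also stand in other lists. Counts adjusted over the list alone used the same p-values, adjusted within 1 list.

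The groups, lists, tests, threshold, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls of each of the first 2 comparisons among genes past the threshold whose arrays did not overlap between the groups, the 3 largest of control lung against spleen, the 5 with the largest smaller change among genes that differed from both other groups, Foxp3, Cd4, Il2ra, Ctla4, Il10, Areg, Il1rl1, Penk and Mmp12, and list members with the smallest p or needed to describe a list. Predicted or non-coding models and antigen receptor segments were passed over in the ranks. Penk was not analysed here, as no row carried its name, and some genes that the rule took are not reported here. Marco, Scgb1a1, Cbx3, Cyp20a1, Eloc, Gins1, Kif20b, Naip2 and Zmpste24, Lag3 in control lung against spleen, and in the closing part Cyp2f2, Scgb3a1, Napsa, Ctss, the clock genes were chosen after their values were seen, as were the lists of control lung against spleen described by their members.

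Alternatives changed the normalisation between arrays (quantile normalisation applied again, or median centring), the floor of dim values, the filter on dim genes, the arrays in the fit, the replicate number as a block, the variance model, the rows per gene, the threshold, the set test and the arrays left out. Under trend and robust moderation camera used the trend alone. Leaving out the 2 arrays low in Xist, the block over the 6 arrays of injured mice, and the macrophage list mean as a covariate were chosen after seeing the data.

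Titles numbered the replicates 1 to 3 in each group, and the numbers were checked by correlating the arrays' deviations from their group means over all genes. Between resolving lung and spleen, arrays of the same number correlated at 0.132 to 0.174 and arrays of different numbers at 0.0175 or less, so the numbers were taken as pairs there, from the data and not from a statement in the labels. Deviations from the mean of 3 arrays sum to 0, so a positive same-number value pulls the others down. A shared batch could give such values too, so shared mice were not shown. Control lung numbers did not meet this rule. Spleen replicates 2 and 3 carry the same name in their descriptions and different titles, and the titles were used. Their columns differed by a median of 0.103, and 0 columns were identical.

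The fit was tested on simulated data with 100 of 21023 genes changed by each of 2 sizes. The changed genes were taken from those with a mean log2 of at least 5, so recovery of dimmer genes was not tested. At a log2 change of 1 it recovered 77% of changed genes for resolving against control lung, 81% for resolving lung against spleen and 79% for control lung against spleen, and at a change of 2 it recovered 96%, 98% and 96%. False calls were 7.98%, 3.24% and 6.42% of calls. A simulated rise of 0.5 in the cell cycle list was called, and it was the 1 list called of 30. Genes were simulated independently of each other, whereas the estimated correlation of this list in the real data was 0.613. So the simulation does not show how many lists would be called where genes are correlated.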

Results

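Gene expression was measured in regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain immune responses. They had been sorted as CD4+ GFP+ cells from C57BL/6 mice aged 8 to 12 weeks that carry a green fluorescent reporter in Foxp3. Tregs came from uninjured lungs (control lung), from lungs recovering from an acute injury caused by bacterial lipopolysaccharide given at 3 mg/kg into the trachea (resolving lung) and from spleens of injured mice (resolving spleen), with 3 arrays per group. Each array gave a log2 expression value for 21023 named genes. Between 44.8% and 47.5% of these genes per array lay above the 95th percentile of 915 olfactory receptor genes, a family that T cells are not known to express, taken as the dim level. A difference from a group below that level in all 3 arrays has only a lower limit and is given as at least that size. The number of arrays limited the precision.

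Foxp3, the transcription factor that defines Tregs, was expressed at 10.67 ± 0.04 (SD, n = 3) on the log2 scale in control lung, 10.58 ± 0.16 (SD, n = 3) in resolving lung and 10.69 ± 0.05 (SD, n = 3) in resolving spleen. Cd4 had group means of 10.92, 10.86 and 11.04. Neither gene differed past the threshold in any comparison with limma (the smallest adjusted p was 0.192). The arrays also held transcripts of other cells. Sftpc, a surfactant protein of alveolar type II epithelium, reached 11.04 in control lung replicate 1. Scgb1a1, a secretory protein of airway cells, stood at 3.41, 6.26 and 7.41 in the spleen arrays. Resolving lung replicate 1 stood apart from replicates 2 and 3 of its group. It had higher levels of the macrophage genes Marco (5.08 against 2.53 and 2.16) and Chil3 (10.03 against 6.90 and 7.12) and of the collagen gene Col1a1 (6.86 against 3.08 and 3.20). Control lung replicate 1 stood apart from replicates 2 and 3 in the means of the endothelium list (4.34 against 2.86 and 2.72) and the fibroblast list (4.04 against 2.62 and 2.58). Xist, the RNA of the inactive X chromosome, was at 2.44 in resolving lung replicate 1 and 2.33 in resolving spleen replicate 1, and between 8.23 and 9.13 in the other 7 arrays. The Y-linked gene Ddx3y was between 6.89 and 8.21 in all 9 arrays. So 7 arrays held Xist and a Y-linked transcript together, which points to RNA of mice of both sexes in each. The labels give no sex. Both arrays low in Xist were from injured mice, so the sex mix may differ between resolving and control lung.

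The first comparison set Tregs of resolving lung against Tregs of uninjured lung, the change that goes with injury and its resolution in 1 organ. Mmp12, the macrophage elastase, was at least 7.17-fold higher in resolving lung (log2 difference of at least 2.84, limma adjusted p = 0.00967), at 6.26 ± 0.57 against 3.08 ± 0.26 (SD, n = 3 each). The control values lay below the dim level in all 3 arrays. Gpnmb, a membrane glycoprotein of phagocytes and some other cells, was 6.89-fold higher, Asb2, a subunit of a ubiquitin ligase, 6.57-fold and C3ar1, the receptor of complement fragment C3a, at least 5.34-fold (adjusted p = 0.0130, 0.0351 and 0.0339). In control lung Asb2 was above the dim level in 1 of 3 arrays and C3ar1 in 0. The deepest falls were in the alveolar epithelial genes Slc34a2, a phosphate transporter (log2 difference -2.94, SE 0.39), and Sftpb (-2.80, SE 0.40) and Sftpa1 (-2.75, SE 0.36), which encode surfactant proteins. Irs2, an adaptor of insulin and cytokine receptors, fell 3.61-fold (log2 difference -1.85, SE 0.15, adjusted p = 0.00967), from 7.42 ± 0.13 to 5.57 ± 0.20 (SD, n = 3 each).

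In all, 96 of 21023 genes passed the threshold, 28 higher and 68 lower in resolving lung. Of these, 8 rises and 26 falls had a fitted difference of at least 2-fold. At an unadjusted p under 0.05 there were 2943 genes. The remaining large rises were in Actg2, a smooth muscle actin (log2 difference 1.41), F2rl3, a thrombin receptor (at least 0.64), Tmc3, a channel-like membrane protein (at least 0.69), and Morrbid, a long non-coding RNA (1.01). Others were Unc119, a chaperone of lipid-modified proteins (0.98), and Parpbp, a DNA repair factor (0.96). Over the alternative settings, the call was lost in 2 of 21 for Mmp12, 5 of 22 for Gpnmb, 11 of 22 for Asb2 and 10 of 21 for C3ar1. It was lost in 15 of 23 for Actg2, 18 of 21 for F2rl3, 10 of 21 for Tmc3 and 13 of 22 for Morrbid. The remaining large falls were in Ramp3, a receptor activity-modifying protein (-2.37), the tubulin Tubb2a (-2.05), the zinc finger gene Zbtb10 (-1.77), the deubiquitinase Usp2 (at least 1.26 lower), the endosomal sorting gene Vps37b (-1.73) and the myosin light chain Myl7 (at least 0.49 lower). Calls of falls were lost too. Their count was 4, 14 and 6 without control lung replicate 1, 2 or 3 and 7, 3 and 5 without spleen replicate 1, 2 or 3. Without resolving lung replicate 1, 2 or 3 it was 38, 23 and 122, and with the 6 lung arrays fitted alone 0. The arrays of the groups did not overlap for any of the 96 genes, which holds for 16.3% of all genes and would hold for 10% by chance.

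**Figure D1:**
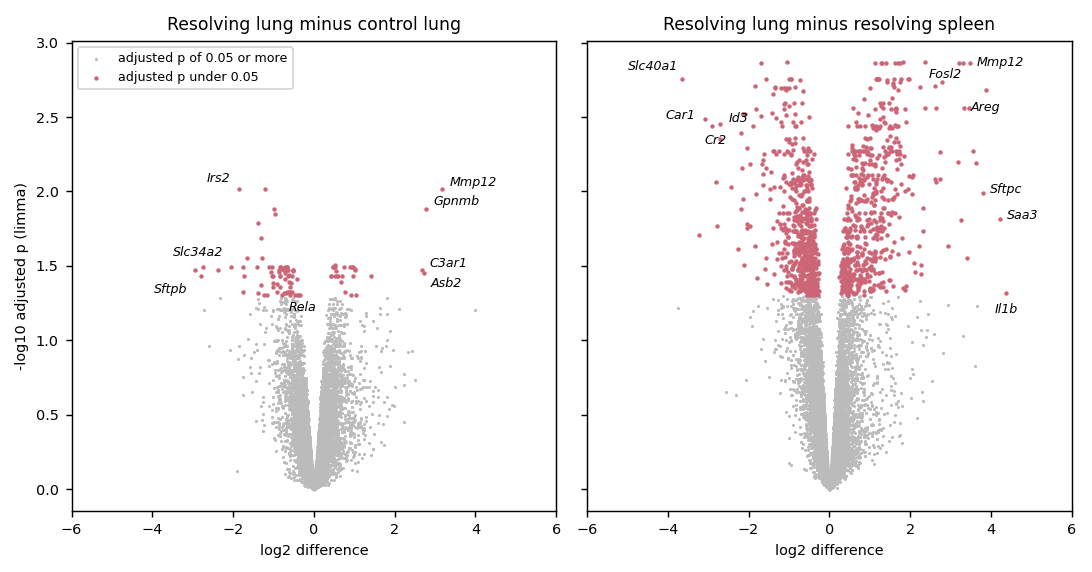
Log2 difference of each of 21023 genes (horizontal axis) against -log10 of its adjusted p from limma (vertical axis), for resolving lung minus control lung on the left and resolving lung minus resolving spleen on the right, with red points for adjusted p under 0.05. On the left 96 genes are red, with Mmp12 and Irs2 among the highest, and on the right 1148.

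Genes of the Treg programme were measured through fixed lists. Of the 18 measured Treg core genes none passed the threshold over all genes (2 higher and 2 lower adjusted over the list alone), and the list did not shift (median 0.05, mean -0.02, camera direction up, adjusted p = 0.502). Il2ra, the high-affinity receptor chain for interleukin-2, was at 0.22 (SE 0.08) and Ctla4, an inhibitory receptor, at 0.10 (SE 0.08), both short of the threshold. The T cell identity list did not shift (median -0.05, camera adjusted p = 0.0919), although 1 member fell over all genes, with 1 higher and 1 lower adjusted over the list alone. The effector Treg list was shifted up, with 24 of 25 members higher (median 0.58, camera adjusted p = 4.69e-09). No member passed over all genes and 13 passed adjusted over the list alone, among them the inhibitory receptor Lag3 (1.46, SE 0.29), the calcium-binding protein S100a4 (0.87, SE 0.21) and the chemokine receptor Cxcr3 (0.63, SE 0.13). The resting or lymphoid Treg list was shifted down, with 20 of 21 members lower (median -0.69, camera adjusted p = 2.25e-09). No member passed over all genes and 8 passed adjusted over the list alone, among them the chromatin organizer Satb1 (-1.42, SE 0.32) and the lymph node homing receptor Ccr7 (-1.55, SE 0.39). The cell cycle list was shifted up with 39 of 40 genes higher (median 0.51, camera adjusted p = 3.87e-13), none past the threshold over all genes and 17 adjusted over the list alone. Hmmr (0.65, SE 0.11), Cenpf (0.59, SE 0.13) and Kif20a (0.76, SE 0.17), all of mitosis, had its smallest p. With an estimated correlation the adjusted p was 0.432 for each of these 3 lists. Resolving lung replicate 1 had the most distant mean in each. The means of replicates 1, 2 and 3 were 8.95, 8.37 and 8.14 for the effector list, 7.14, 8.14 and 8.32 for the resting list and 7.66, 7.30 and 7.29 for the cell cycle list. The median of a shifted list without 1 array is given wherever it moved by over 1.5 times. The median was 0.32 for the effector list, -0.33 for the resting list and 0.34 for the cell cycle list without resolving lung replicate 1.

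The tissue Treg and repair list was shifted up with 17 of 24 members higher (median 0.24, camera adjusted p = 0.0389, adjusted p = 0.566 with an estimated correlation). No member passed over all genes and 1 passed adjusted over the list alone. Areg, which encodes the epithelial growth factor amphiregulin, was at 0.15 (SE 0.35), Il1rl1, the interleukin-33 receptor, at -0.55 (SE 0.17) and the suppressive cytokine Il10 at 0.70 (SE 0.42), none past the threshold. Growth factor and matrix genes were shifted up with 32 of 39 higher (median 0.28, camera adjusted p = 1.03e-04, adjusted p = 0.464 with an estimated correlation). Mmp12 was their single member past the threshold, over all genes and adjusted over the list alone, while the protease genes Mmp19 (at least 0.76) and Adam8 (0.81, SE 0.23) did not pass. Chemokine genes were shifted up with 18 of 22 higher (median 0.60, camera adjusted p = 0.00237, adjusted p = 0.531 with an estimated correlation). None passed over all genes and 2 passed adjusted over the list alone, Cxcl16 (2.11, SE 0.37) and Xcl1 (at least 0.92). In resolving lung replicates 1, 2 and 3 the mean of the chemokine list was 5.64, 3.99 and 3.95, that of the growth factor list 5.38, 4.53 and 4.52 and that of the tissue Treg list 7.83, 7.19 and 6.94. The helper T cell lineage list (median 0.05, camera adjusted p = 0.129) and the chemokine and homing receptor list (median 0.06, camera adjusted p = 0.162) did not shift. None of their members passed over all genes, and adjusted over the list alone 6 and 3 were higher and 2 and 1 lower. Bcl6, the follicular lineage repressor, stood at -1.19 (SE 0.21), not past the threshold. The camera adjusted p of the tissue Treg list was 0.0966, 0.0883 and 0.359 without control lung replicate 2, control lung replicate 3 and resolving lung replicate 1. That of the chemokine list was 0.190 without resolving lung replicate 1, and the chemokine and homing receptor list was then called up (adjusted p = 0.0292). The median was 0.94 for chemokines without control lung replicate 1. It was -0.011 for the tissue Treg list, 0.056 for growth factors and 0.12 for chemokines without resolving lung replicate 1. It was 0.93 for chemokines without resolving lung replicate 2. It was 0.39 for the tissue Treg list, 0.42 for growth factors and 1.07 for chemokines without resolving lung replicate 3.

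NF-kB genes were shifted down with 14 of 22 lower (median -0.12, camera adjusted p = 0.0161, adjusted p = 0.457 with an estimated correlation). Over all genes 3 members fell, the apoptosis inhibitor Birc3 (-0.53, adjusted p = 0.0339) and the subunits Rel (-0.70, adjusted p = 0.0478) and Rela (-0.35, adjusted p = 0.0498), and 6 fell and 1 rose adjusted over the list alone. The immediate early list was shifted down (median -0.19, camera adjusted p = 0.00267, adjusted p = 0.432 with an estimated correlation), with the AP-1 subunit Fosl2 its member past the threshold (-1.02, adjusted p = 0.0372), over all genes and adjusted over the list alone. Interferon-stimulated genes (median -0.05, mean -0.01, camera direction up, adjusted p = 0.977) and heat shock genes (median 0.11, camera adjusted p = 0.158) did not shift, and no member passed over all genes (1 higher and 1 lower interferon-stimulated gene adjusted over the list alone, 0 heat shock genes). Metabolic lists were shifted up by small amounts: oxidative phosphorylation (median 0.18, camera adjusted p = 4.18e-05), glycolysis (median 0.12, camera adjusted p = 0.0368) and cholesterol synthesis (median 0.12, camera adjusted p = 0.00974), each with an adjusted p of 0.432 with an estimated correlation. Among them only Fdft1, squalene synthase, passed over all genes (0.43, adjusted p = 0.0372), and 2 cholesterol genes rose adjusted over the list alone, against 0 in the other lists. Ribosomal protein genes were shifted down (median -0.04, camera adjusted p = 0.0333, adjusted p = 0.531 with an estimated correlation), none past the threshold over all genes or adjusted over the list alone. In resolving lung replicates 1, 2 and 3 the list mean was 7.77, 7.52 and 7.46 for oxidative phosphorylation and 6.85, 6.73 and 6.61 for glycolysis, against 7.38, 7.36 and 7.46 and 6.62, 6.58 and 6.58 in control lung. Leaving out 1 array ended some of these calls. The camera adjusted p of the NF-kB list was 0.167 without resolving lung replicate 3, and that of the cholesterol list 0.201 without resolving lung replicate 2. For glycolysis it was 0.0729, 0.0961, 0.161 and 0.0718 without control lung replicate 2, control lung replicate 3, resolving lung replicate 1 and resolving lung replicate 2. For ribosomal proteins it was 0.129 and 0.301 without control lung replicate 1 and resolving lung replicate 3. The heat shock list was called up with an adjusted p of 0.00662 without control lung replicate 1. The immediate early list mean was 7.76, 7.47 and 7.47 in resolving lung and 7.83, 7.69 and 7.46 in control lung, so the groups overlapped. The median was -0.021 for ribosomal proteins without control lung replicate 1. It was 0.12 for oxidative phosphorylation without control lung replicate 2. It was -0.062 for ribosomal proteins without control lung replicate 3. It was -0.18 for NF-kB genes, 0.090 for oxidative phosphorylation, 0.061 for glycolysis and -0.071 for ribosomal proteins without resolving lung replicate 1. It was 0.072 for glycolysis without resolving lung replicate 2. It was -0.026 for NF-kB genes and -0.0052 for ribosomal proteins without resolving lung replicate 3.

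Markers of other cells moved in different directions. The epithelium list was shifted down with 20 of 21 lower (median -0.83, camera adjusted p = 1.99e-09, adjusted p = 0.432 with an estimated correlation). Over all genes 3 members fell, Slc34a2, Sftpb and Sftpa1, and 7 fell adjusted over the list alone, Lamp3 of type II cells among the largest (-2.72, SE 0.49, above the dim level in 2 of 3 resolving lung arrays). The B cell list was shifted down (median -0.57, camera adjusted p = 1.41e-05), as were the conventional CD4 T cell list (median -0.36, camera adjusted p = 0.00162), 8 of whose 13 measured members stand in other lists, and the CD8 T or NK cell list (median -0.31, camera adjusted p = 0.0333). In each of these the adjusted p was 0.432 with an estimated correlation, no member passed over all genes and 3 fell adjusted over the list alone, with 1 member of the conventional list higher. The macrophage list was shifted up (median 0.71, camera adjusted p = 0.0284, adjusted p = 0.652 with an estimated correlation), as were the neutrophil list (median 0.12, camera adjusted p = 0.0438, adjusted p = 0.559 with an estimated correlation) and the erythroid and platelet list (median 0.73, camera adjusted p = 0.0297, adjusted p = 0.432 with an estimated correlation). No member of these 3 lists passed over all genes, and 1 neutrophil gene passed adjusted over the list alone. The macrophage list mean was 6.30, 4.30 and 4.29 in resolving lung replicates 1, 2 and 3, and between 3.93 and 4.97 in control lung. The endothelium (median 0.02, mean -0.08, camera direction down, adjusted p = 0.666), fibroblast (median 0.31, camera adjusted p = 0.169), dendritic cell (median 0.14, camera adjusted p = 0.383), mast cell (median -0.02, camera adjusted p = 0.338) and sex-linked lists (median 0.19, mean -0.21, camera direction up, adjusted p = 0.769) did not shift, with 0 members past the threshold over all genes or adjusted over the list alone. In resolving lung replicates 1, 2 and 3 the neutrophil list mean was 4.19, 3.33 and 3.29 (control lung 3.55, 3.13 and 2.96) and the erythroid and platelet list mean 4.03, 5.06 and 3.64 (control lung 3.66, 3.20 and 3.00). For the macrophage list the camera adjusted p was 0.533 and 0.902 without control lung replicate 3 and resolving lung replicate 1. That of the neutrophil list was 0.105, 0.512, 0.482, 0.0555 and 0.0518 without control lung replicate 2, control lung replicate 3, resolving lung replicate 1, spleen replicate 1 and spleen replicate 3. For the erythroid and platelet list it was 0.0753, 0.112 and 0.0870 without control lung replicate 2, control lung replicate 3 and resolving lung replicate 2. For the CD8 T or NK cell list it was 0.0966, 0.0628, 0.0798 and 0.0734 without control lung replicate 2, control lung replicate 3, resolving lung replicate 1 and resolving lung replicate 2. Some lists that had not shifted were called with 1 array left out. The adjusted p was 0.00488 up, 0.0447 down and 0.0168 down without control lung replicate 1, control lung replicate 3 and resolving lung replicate 1 for endothelium. It was 4.81e-04 up, 0.0134 up and 0.0312 up without control lung replicate 1, resolving lung replicate 2 and resolving lung replicate 3 for fibroblasts. For dendritic cells it was 0.0479 down and 0.0317 up without resolving lung replicate 1 and resolving lung replicate 3. The conventional CD4 T cell list mean was 6.59, 7.29 and 7.44 in resolving lung and 7.61, 7.73 and 7.51 in control lung. The median was -0.35 for epithelium and 0.46 for neutrophils without control lung replicate 1. It was -0.18 for the CD8 T or NK cell list without control lung replicate 2. It was 0.060 for neutrophils without control lung replicate 3. It was -0.14 for the conventional CD4 T cell list, -0.074 for the CD8 T or NK cell list, -0.012 for macrophages, 0.031 for neutrophils and 0.21 for the erythroid and platelet list without resolving lung replicate 1. It was -0.57 for the conventional CD4 T cell list, 0.21 for neutrophils and 0.37 for the erythroid and platelet list without resolving lung replicate 2. It was -0.54 for the CD8 T or NK cell list, 0.24 for neutrophils and 1.16 for the erythroid and platelet list without resolving lung replicate 3.

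**Figure D2:**
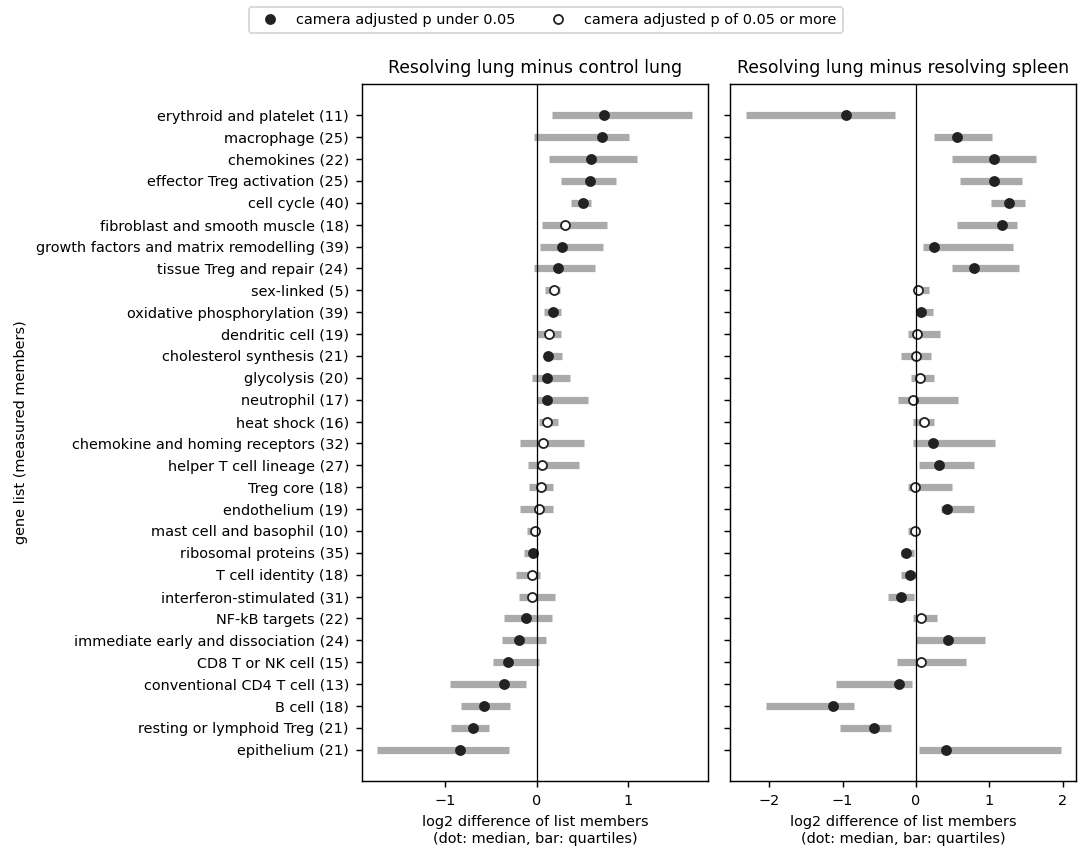
Median log2 difference (dots) and quartiles (grey bars) of the measured members of 30 gene lists, for resolving lung minus control lung on the left and resolving lung minus resolving spleen on the right, with the number of measured members in parentheses and filled dots for a camera adjusted p under 0.05. Cell cycle genes lie above 0 in both panels (0.51 and 1.27), and epithelial genes lie below 0 on the left (-0.83) and above 0 on the right (0.41).

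With limma and camera (preset correlation 0.01) 96 genes and 19 of 30 lists (11 up, 8 down) were called, and 0 lists were called with an estimated correlation (0 at an unadjusted p under 0.05) or with fry (8 at an unadjusted p under 0.05). The gene count was 5, 25 and 8 without control lung replicate 1, 2 or 3, 59, 29 and 212 without resolving lung replicate 1, 2 or 3, 11, 4 and 7 without spleen replicate 1, 2 or 3, 9 without both arrays low in Xist, 363 among genes with a mean log2 of at least 5, and 0 when the 6 lung arrays were fitted alone (2344 at an unadjusted p under 0.05).

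The next comparison set Tregs of resolving lung against Tregs of spleens of injured mice, the difference between the injured organ and a lymphoid organ. The lung arrays held more transcript of the checkpoint receptor Ctla4 (log2 difference 1.14, SE 0.08, limma adjusted p = 0.00136) and of Areg (3.33, SE 0.35, adjusted p = 0.00274). They also held more of the interleukin-33 receptor Il1rl1 (1.50, SE 0.17, adjusted p = 0.00364) and of Il10 (1.82, SE 0.42, adjusted p = 0.0446). Areg was at 8.25 ± 0.56 in lung and 4.92 ± 0.63 in spleen (SD, n = 3 each). The mitotic gene Cenpf was higher in lung (1.75, SE 0.13, adjusted p = 0.00136). The iron exporter Slc40a1 was lower in the lung arrays (-3.65, SE 0.31, adjusted p = 0.00176), above the dim level in 1 of 3 of them. Whether Tregs or other cells of the samples held it, or the transcripts that were higher in lung, was not tested.

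In all, 1148 genes differed, 556 higher and 592 lower in lung, of which 257 and 120 had a fitted difference of at least 2-fold. The 10 largest rises by the fitted difference were in the inflammatory cytokine Il1b (4.37, SE 1.03), the acute phase gene Saa3 (at least 3.25), the chemokines Cxcl16 (at least 3.42) and Ccl3 (3.63) and the surfactant gene Sftpc (3.80). The others were Acod1, the enzyme that makes itaconate (at least 2.58), Mmp12 (at least 2.87), C3ar1 (at least 2.45), the lectin receptor Clec4e (at least 2.47) and Areg. Il1b was uneven in resolving lung, at 10.01, 6.59 and 6.40 in replicates 1 to 3, against 4.03, 3.44 and 2.44 in spleen. The 10 largest falls by the fitted difference were in Slc40a1 and the erythroid genes Ermap (at least 1.90 lower), Car1 (at least 2.62 lower), Rhag (at least 1.77 lower) and Ank1 (at least 1.17 lower). The others were the B cell complement receptor Cr2 (-2.90), the adhesion molecule Vcam1 (-2.78), Spic, a transcription factor of red pulp macrophages (-2.71), the neurturin receptor Gfra2 (at least 1.57 lower) and the integrin Itgad (at least 1.35 lower). Which cells held the transcripts of either set was not tested. The order of either set rests in part on values below the dim level. Slc40a1, Cr2 and Spic were above it in 1 of 3 lung arrays. In spleen Il1b was above it in 1 of 3 arrays and Sftpc in 2.

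The Treg core list did not shift (median -0.02, mean 0.19, camera direction up, adjusted p = 0.246). Over all genes 3 of its members were higher, Ctla4, the phosphatase Dusp4 (1.88) and Rgs1 (0.95), and 1 was lower, Izumo1r, the folate receptor family member of Tregs (-1.13), with 5 and 2 adjusted over the list alone. Il2ra was at -0.15 (SE 0.08). The effector Treg list was shifted up, with 17 of 25 members higher over all genes and 18 adjusted over the list alone (median 1.07, camera adjusted p = 9.68e-18). They included the costimulator Icos (1.16), the annexin Anxa2 (1.26) and granzyme B, Gzmb (1.73). The tissue Treg and repair list was shifted up, with 9 of 24 members higher over all genes and 14 adjusted over the list alone (median 0.80, camera adjusted p = 8.47e-14). Among them were the chemokine receptor Ccr2 (1.82), Areg, the transcription factor Nfil3 (1.65) and Il1rl1. Of 40 cell cycle genes 35 were higher over all genes and 39 adjusted over the list alone, and the list was shifted up (median 1.27, camera adjusted p = 2.48e-37), with Ccne2 at 1.39, Hmmr at 1.24 and Nusap1 at 1.57. With an estimated correlation the adjusted p was 0.187 for each of these 3 lists. The resting or lymphoid list was shifted down with 20 of 21 lower (median -0.57, camera adjusted p = 7.98e-07, adjusted p = 0.384 with an estimated correlation). Its members Id3, a transcription regulator (-1.70, adjusted p = 0.00312), and Igfbp4 (-1.03, adjusted p = 0.0153) fell, over all genes and adjusted over the list alone. The T cell identity list was shifted down by a small amount (median -0.09, camera adjusted p = 0.0323, adjusted p = 0.187 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. Its camera adjusted p was 0.0804, 0.0608, 0.0559 and 0.0762 without resolving lung replicate 1, resolving lung replicate 3, spleen replicate 1 and spleen replicate 3. The resting list mean was 7.14, 8.14 and 8.32 in resolving lung and 8.61, 8.56 and 8.52 in spleen. The median was -0.24 for the resting list without resolving lung replicate 1. It was -0.15 for the T cell identity list without resolving lung replicate 2.

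Among chemokine and homing receptors 8 members rose and 1 fell (11 and 2 adjusted over the list alone), with Ccr2, Cxcr4 (1.42) and the integrin Itgae (1.44) among those that rose. That list was shifted up (median 0.24, camera adjusted p = 5.63e-05, adjusted p = 0.105 with an estimated correlation). Helper lineage genes were shifted up (median 0.32, camera adjusted p = 4.67e-05, adjusted p = 0.187 with an estimated correlation). Over all genes 6 rose and 8 adjusted over the list alone, including the interleukin-18 receptor genes Il18rap (1.25) and Il18r1 (0.87) and the aryl hydrocarbon receptor Ahr (1.12). Chemokines were shifted up (median 1.06, camera adjusted p = 7.49e-07), as were growth factor and matrix genes (median 0.25, camera adjusted p = 1.79e-06), both with an adjusted p of 0.377 with an estimated correlation. Over all genes 3 chemokines rose, Cxcl16, Ccl3 and Ccl9 (2.27), and 5 adjusted over the list alone. Of the growth factor and matrix genes 6 rose over all genes and 8 adjusted over the list alone, among them Mmp12, Areg, Adam8 (1.71) and the urokinase receptor Plaur (2.04). The list mean was 5.64, 3.99 and 3.95 for chemokines and 5.38, 4.53 and 4.52 for growth factors in resolving lung, against 3.35, 3.34 and 3.13 and 4.14, 4.06 and 3.94 in spleen. The median was 0.44 for chemokine and homing receptors, 0.15 for the helper lineage list, 0.43 for chemokines and 0.098 for growth factors without resolving lung replicate 1. It was 0.18 for the helper lineage list without resolving lung replicate 2. It was 0.41 for growth factors without resolving lung replicate 3.

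The immediate early list was shifted up (median 0.44, camera adjusted p = 6.62e-04, adjusted p = 0.335 with an estimated correlation). Over all genes 6 members rose, among them Fosl2 (2.38), the nuclear receptor Nr4a1 (1.17) and the stress factor Atf3 (3.18), and 2 fell, among them the phosphatase Dusp2 (-0.53), with 12 and 4 adjusted over the list alone. Per the labels' protocols, lungs had been digested with enzyme and spleens dissociated mechanically. NF-kB genes did not shift (median 0.07, camera adjusted p = 0.162), with the inhibitor Tnfaip3 higher (1.68, adjusted p = 0.0104) and Rela lower (-0.42, adjusted p = 0.00606). In that list 3 members rose and 2 fell over all genes, and 6 and 3 adjusted over the list alone. Interferon-stimulated genes were shifted down (median -0.20, camera adjusted p = 6.62e-04, adjusted p = 0.105 with an estimated correlation). Over all genes 3 members fell and 1 rose (12 and 2 adjusted over the list alone), with Ifit2 at -0.89 and Usp18 at -0.96. Oxidative phosphorylation genes were shifted up (median 0.07, camera adjusted p = 0.0352, adjusted p = 0.631 with an estimated correlation) and ribosomal protein genes down (median -0.13, camera adjusted p = 0.00118, adjusted p = 0.377 with an estimated correlation), with no member of either past the threshold over all genes or adjusted over the list alone. The heat shock (median 0.11, camera adjusted p = 0.0745), glycolysis (median 0.06, camera adjusted p = 0.494) and cholesterol synthesis lists (median 0.00, mean -0.02, camera direction down, adjusted p = 0.829) did not shift. Over all genes 1 glycolysis gene fell, the phosphofructokinase Pfkm (-0.77), and 1 cholesterol gene rose. Adjusted over the list alone 3 heat shock, 2 glycolysis and 1 cholesterol gene rose and 2 glycolysis genes fell. The camera adjusted p of the oxidative phosphorylation list was 0.934, 0.0602 and 0.0912 without resolving lung replicate 1, spleen replicate 1 and spleen replicate 3. The NF-kB list was called with an adjusted p of 0.0243 up without resolving lung replicate 3. The median was 0.039 for oxidative phosphorylation without resolving lung replicate 1. It was 0.15 for oxidative phosphorylation and -0.072 for ribosomal proteins without resolving lung replicate 3. It was 0.043 for oxidative phosphorylation and -0.058 for ribosomal proteins without spleen replicate 1.

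B cell markers were shifted down, with 9 of 18 lower over all genes and 16 adjusted over the list alone (median -1.13, camera adjusted p = 7.60e-15, adjusted p = 0.187 with an estimated correlation), among them Cr2, Cd22 (-2.04) and Cd79a (-1.65). The erythroid and platelet list was shifted down (median -0.95, camera adjusted p = 0.00440, adjusted p = 0.335 with an estimated correlation), with Car1 its member past the threshold over all genes and 2 adjusted over the list alone. The conventional CD4 T cell list was shifted down (median -0.23, camera adjusted p = 0.00141, adjusted p = 0.377 with an estimated correlation), 2 members over all genes and 4 adjusted over the list alone. Epithelial genes were shifted up (median 0.41, camera adjusted p = 1.10e-04, adjusted p = 0.415 with an estimated correlation), 6 of 21 past the threshold over all genes and 7 adjusted over the list alone, with Sftpa1 higher by at least 2.28, Sftpb at 2.74 and the mucin Muc1 at 1.28. The fibroblast (median 1.17, camera adjusted p = 7.70e-04), endothelium (median 0.42, camera adjusted p = 0.00274) and macrophage lists (median 0.56, camera adjusted p = 0.00440) were shifted up with no measured member past the threshold over all genes or adjusted over the list alone. Of 30 macrophage list members 25 were measured. Their adjusted p was 0.560, 0.623 and 0.631 with an estimated correlation. In resolving lung replicates 1, 2 and 3 the list mean was 4.85, 2.75 and 2.86 for fibroblasts, 3.96, 2.90 and 2.81 for endothelium and 6.30, 4.30 and 4.29 for macrophages. In the spleen arrays the list mean was 2.37, 2.36 and 2.46 for fibroblasts, 2.57, 2.61 and 2.63 for endothelium and 4.57, 4.09 and 4.11 for macrophages. The neutrophil list did not shift (median -0.04, mean 0.14, camera direction up, adjusted p = 0.892), with Clec4d higher (at least 1.92, adjusted p = 0.0231) and Mpo, the myeloperoxidase gene, lower (adjusted p = 0.0156, above the dim level in 0 lung and 2 spleen arrays), and 2 higher and 2 lower adjusted over the list alone. The dendritic cell (median 0.01, camera adjusted p = 0.699), CD8 T or NK cell (median 0.07, camera adjusted p = 0.640), mast cell (median -0.01, camera adjusted p = 0.831) and sex-linked lists (median 0.02, camera adjusted p = 0.892) did not shift. None of their members passed over all genes, and 3 CD8 T or NK cell genes were higher and 1 lower adjusted over the list alone. Without resolving lung replicate 1 the camera adjusted p was 0.124 for the fibroblast, 0.215 for the endothelium and 0.629 for the macrophage list, and the dendritic cell list was called down (adjusted p = 0.0342). The median was -0.065 for the conventional CD4 T cell list, 0.24 for epithelium, 0.24 for fibroblasts, 0.15 for endothelium and 0.15 for macrophages without resolving lung replicate 1. It was 0.92 for macrophages without resolving lung replicate 2. It was -0.61 for the erythroid and platelet list, -0.47 for the conventional CD4 T cell list and 0.89 for macrophages without resolving lung replicate 3. It was -0.43 for the erythroid and platelet list without spleen replicate 1.

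**Figure D3:**
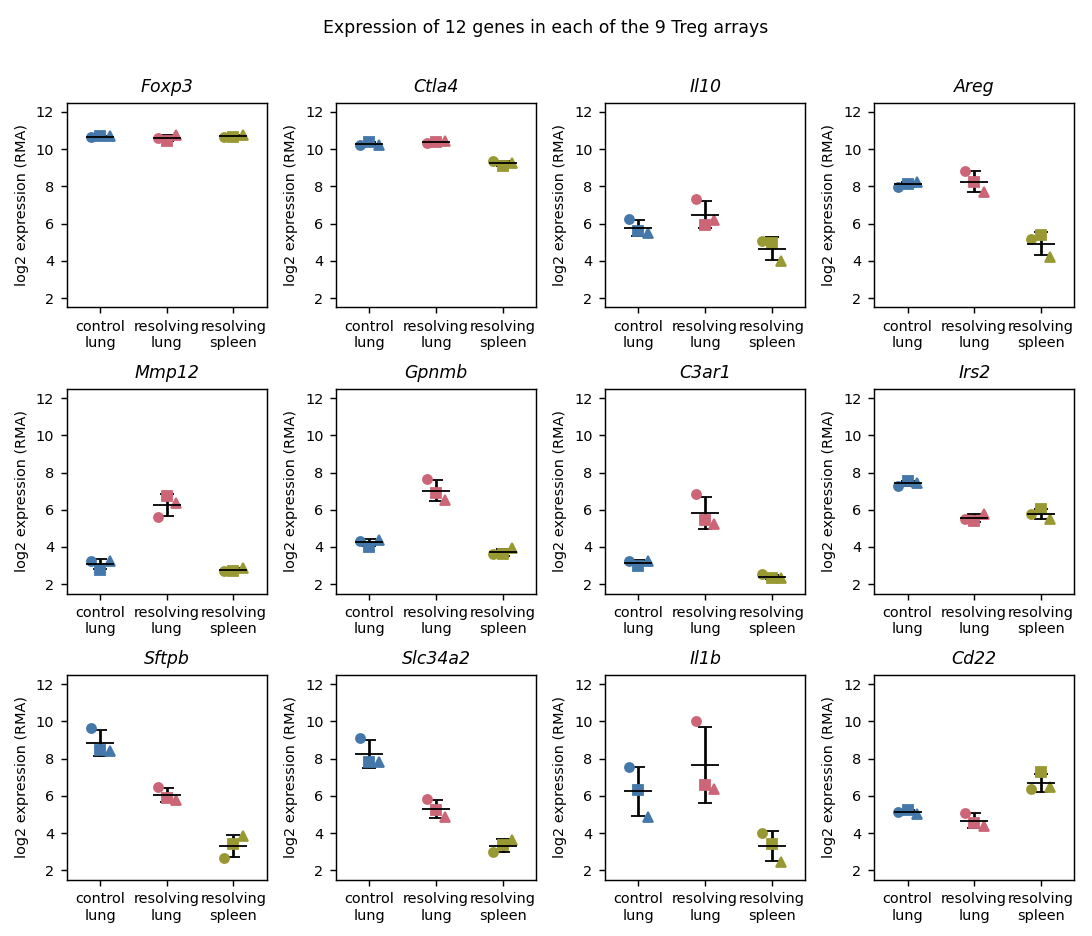
Log2 expression of 12 genes (vertical axis) in each of the 9 arrays, by group, with circles, squares and triangles for replicates 1, 2 and 3 and black lines for the group mean ± SD (n = 3). Foxp3 lies between 10.58 and 10.69 in the group means, Areg is at 8.11 and 8.25 in the lung groups and 4.92 in spleen, and Mmp12, Gpnmb and C3ar1 are higher in resolving lung than in both other groups.

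With limma and camera 1148 genes and 20 of 30 lists (13 up, 7 down) were called, and 0 lists were called with an estimated correlation (8 at an unadjusted p under 0.05) and 10 with fry. The replicate numbers were taken to pair lung and spleen arrays, from their correlations alone. With the number as a block over the 6 arrays of injured mice 175 genes were called. The block leaves fewer degrees of freedom and gave 3777 genes at an unadjusted p under 0.05 with limma, against 3944 without it. Its adjusted p lay above the threshold, between 0.0534 and 0.146, for Acod1, Ahr, Ank1, Bzw2, Car1, Ccl9, Cd22, Cd79a, Clec4d, Clec4e, Cr2, Cxcr3, Cxcr4, Dusp2, Ermap, Fgd3, Gzmb, Icos, Ifit2, Igfbp4, Il10, Il18r1, Il18rap, Il1b, Itgad, Itgae, Morrbid, Mpo, Muc1, Nusap1, Plaur, Rela, Rhag, Saa3, Sftpb, Sftpc, Simc1, Tnfaip3, Usp18 and Usp36, and at 0.0496 for Areg, Ctla4, Il1rl1, Mmp12, Cenpf and Slc40a1. The count was 716 without resolving lung replicate 2, 508, 662 and 584 without spleen replicate 1, 2 or 3, 527 without both arrays low in Xist and 704 when the 6 arrays were fitted alone without a block.

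Genes that differed in the same direction from both other groups were then counted. Resolving lung was higher than both for 13 genes: Mmp12, Gpnmb, C3ar1, Morrbid, Parpbp, Gins1, Naip2, Kif20b, Tmc3, Eloc, Cyp20a1, Cbx3 and Zmpste24. The smaller of the differences was at least 2.84 for Mmp12 and 2.42 for C3ar1, which lay below the dim level in all control lung and spleen arrays, and 2.79 for Gpnmb, 1.01 for Morrbid and 0.96 for Parpbp. It was lower than both for 6 genes. Of these the rule for named genes took the translation regulator Bzw2 (-0.62 against control lung and -0.51 against spleen), Fgd3 (-0.59 and -0.44), Simc1 (-0.74 and -0.42), Usp36 (-0.53 and -0.37) and Rela (-0.35 and -0.42). The other was Snora28, which the rule passed over because its name marks a small nucleolar RNA. With the replicate number as a block over the 6 arrays of injured mice, 5 of the 13 higher genes were still called against spleen, Mmp12, Gpnmb, C3ar1, Parpbp and Kif20b (adjusted p = 0.0496). The other 8 and all 6 lower genes were not (adjusted p of 0.0612 to 0.149). Independent lists would share 0.741 and 1.91 genes. In 50 simulated data sets with no change and shared resolving lung arrays 0 genes passed both tests in either direction. As 0 genes on average were called there in resolving against control lung, this value does not show how far shared arrays raise the overlap. Part of the excess may come from the shared arrays. The counts higher and lower than both were 1 and 0, 3 and 0, and 2 and 0 without control lung replicate 1, 2 or 3, 15 and 1, 6 and 1, and 44 and 44 without resolving lung replicate 1, 2 or 3, and 3 and 0, 1 and 0, and 2 and 0 without spleen replicate 1, 2 or 3.

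Control lung against resolving spleen, where organ and injury differ together, gave context. The control lung arrays were higher in Areg (3.18, SE 0.35, limma adjusted p = 0.00189), Il1rl1 (2.04, SE 0.17, adjusted p = 6.75e-04) and Ctla4 (1.04, SE 0.08, adjusted p = 4.43e-04) and lower in Il2ra (-0.37, SE 0.08, adjusted p = 0.0364). Il10 (1.12, SE 0.42) and Mmp12, below the dim level in all arrays of both groups, did not pass. The largest rises were in Sftpc (6.40, SE 0.59), Sftpb (5.54, SE 0.40) and Sftpa1 (at least 5.03), and the largest falls included those in the red cell gene Slc4a1 (at least 3.87 lower) and in Slc40a1 (at least 3.33 lower). In all, 1295 genes differed, 561 higher and 734 lower in control lung. Cell cycle genes were shifted up, 20 of 40 higher over all genes and 28 adjusted over the list alone (median 0.83, camera adjusted p = 2.48e-21), as were immediate early genes, 9 and 16 higher and 3 and 4 lower (median 0.84, camera adjusted p = 8.48e-07), both with an adjusted p of 0.260 with an estimated correlation. The effector Treg list (median 0.61, camera adjusted p = 1.10e-06, adjusted p = 0.469 with an estimated correlation) and the tissue Treg list (median 0.52, camera adjusted p = 1.14e-07, adjusted p = 0.299 with an estimated correlation) were shifted up too, with 8 and 8 members higher over all genes and 16 and 12 adjusted over the list alone. Lag3 was the 1 effector member that was lower over all genes (-1.49), and adjusted over the list alone 2 effector members and 1 tissue Treg member were lower. The gene count was 752 and 798 without control lung replicate 1 or 3 and 719, 807 and 681 without spleen replicate 1, 2 or 3. Of 30 lists 16 were called (12 up, 4 down). The count was 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 10 with fry.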

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

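The tests of the explanations below, except the counts over other splits of the arrays, were chosen after the results were seen.

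Signal outside the named genes passed the same threshold: of 10294 rows without a gene name here, 14 differed between resolving and control lung (3 higher), 185 between resolving lung and spleen (42 higher) and 219 between control lung and spleen (75 higher). Unmeasured list members may be among these rows, as 636 of 730 list genes were measured.

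Alveolar type II transcripts were lower in resolving than in control lung, with Sftpc, the most abundant, at 10.23 in control lung, 7.63 in resolving lung and 3.83 in spleen. Of their excess over spleen in control lung, the 6 type II genes at least 2-fold over spleen there (Sftpc, Sftpb, Sftpa1, Sftpd, Lamp3 and Slc34a2) kept 5.99% to 17.4% in resolving lung, against 58.9% for Cyp2f2 and 60.8% for Scgb1a1, which airway secretory cells express; Napsa (-22.5%) and Scgb3a1 (41.6%) were below that 2-fold rule, which was set after the shares were seen. Fewer carried-over cells of every kind would lower both sets alike, whereas the within-array difference of airway minus type II genes rose from -0.17 ± 0.26 to 1.80 ± 0.75 (SD, n = 3 each), a change of 1.98 that argues against it (1.98 with Cyp2f2 alone and 1.97 with Scgb1a1 alone); a first test, the macrophage members above the dim level (median change 0.71, quartiles -0.34 to 1.34, 10 of 15 positive), had not decided this and was replaced. The airway side rests on 2 genes, whose changes were -0.61, SE 0.43 and -0.62, SE 0.91, and the share of Scgb1a1 rests on an uneven spleen baseline (3.41, 6.26 and 7.41). Carried-over RNA of type II cells, less of it in resolving lung, would give the like shares of type II genes and may be the source. The CD4+ GFP+ gate was meant to leave out intact type II cells, but the purity of the sort was not tested. A change of surfactant gene expression in the injured lung's epithelium stays open and was not tested.

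Mmp12, Gpnmb and C3ar1 were higher in resolving lung than in both other groups, where Mmp12 and C3ar1 lay below the dim level in all 6 arrays, so that their fitted changes rest on background there. Without resolving lung replicate 1, whose macrophage list mean was the highest, all 3 stayed past the threshold (smallest log2 change 2.18, for C3ar1), which argues against that array as the whole source. With the macrophage list mean as a covariate the changes were 3.38 for Mmp12, 2.60 for Gpnmb and 2.35 for C3ar1 (limma adjusted p = 0.00360, 0.0137 and 0.0137), and the linear excess over control in replicates 2 and 3, relative to replicate 1, was 2.44 and 1.82 for Mmp12, 0.564 and 0.416 for Gpnmb and 0.335 and 0.270 for C3ar1, against at most 0.309 for the 21 macrophage list genes raised 2-fold in replicate 1 (highest in Ctss, median of means 0.0436). These ratios were looked at before the covariate test was chosen. The macrophage genes were picked for their rise in replicate 1, which lowers their ratios. The 3 genes were picked for passing limma against both groups, which favours rises in all 3 arrays and so raises theirs. The excess of Mmp12 was larger in replicates 2 and 3 than in replicate 1, which argues against macrophages of the replicate 1 kind for Mmp12. For Gpnmb, whose gap was in part built in, and for C3ar1, whose range overlaps that of Ctss, the explanations cannot be told apart. Macrophages in another state, or expression by lung Tregs themselves, may each be the source, and neither was tested. The CD4+ GFP+ gate was meant to leave out intact macrophages, but the purity of the sort was not tested.

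The immediate early list was higher in both lung groups than in spleen, with a median of 0.44 for resolving lung and 0.84 for control lung. Enzymatic digestion of lung against mechanical dissociation of spleen could be the source, and a difference between the organs' Tregs could be as well. Digestion went with organ in every array, so the explanations cannot be told apart. Within the lung, where both groups were digested, the list's median was -0.19 in resolving against control lung (camera adjusted p = 0.00267, adjusted p = 0.432 with an estimated correlation).

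Other splits of the arrays were counted for each comparison. For resolving against control lung the real split gave 96 genes and the highest of the other splits 0, as limma counted them (1 of 10 splits as large), and 19 lists against 19 (2 of 10). For resolving lung against spleen they were 1148 genes against 1 (1 of 10) and 20 lists against 19 (1 of 10), and the 3 other splits that part every numbered pair gave at most 0 genes and 19 lists. For control lung against spleen they were 1295 genes against 0 (1 of 10) and 16 lists against 12 (1 of 10). With 10 splits a share under 0.05 cannot be reached. Every other split called lists too, at least 9, 8 and 4 in these comparisons. So a list call at the preset correlation does not by itself show a difference between the groups. Of 100 regroupings of the 9 arrays, 1, the real one, gave as many as 13 genes higher in resolving lung than in both other groups (highest other 1). The real one was also the 1 with as many as 6 lower (highest other 0). These counts argue only against 9 arrays that hold no groups at all. The regroupings mixed lung with spleen and did not keep the pairs of lung and spleen arrays, and the other splits of single comparisons called at most 1 gene, so the regroupings do not show how many genes chance would bring past both tests where the groups differ. With the number as a block over the 6 arrays of injured mice 5 of the 13 and 0 of the 6 genes were called against spleen (highest adjusted p 0.149).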

How the results depend on the processing

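Leaving out the 2 arrays low in Xist, the block over 6 arrays and the macrophage covariate were chosen after the result was seen. Of 323 results of named genes 146 were called, 55 of these in every setting run, and none of the 146 changed direction. Counts follow in the order resolving against control lung, resolving lung against spleen, control lung against spleen, higher than both and lower than both, with those within 1.5 times left out, and the cause was not tested unless given. Filters on dim genes, which leave fewer genes to adjust over, gave 363 genes, 12 lists, 56 higher and 47 lower (mean log2 of at least 5) and 434, 9, 67 and 59 (at least 6 in 3 arrays). Fitting only the 2 groups, with fewer degrees of freedom, gave 0 (2344 at an unadjusted p under 0.05) and 704. Without moderation of the variances the counts were 0 (2476 at an unadjusted p under 0.05), 387, 553, 0 and 0. Array weights gave 63 in the first. Median centring left 1 lower than both and testing every row on its own 2. A threshold of 0.01 gave 3, 351, 434, 1 and 0, and a 2-fold minimum 34, 377, 335, 4 and 0. The replicate block over 9 arrays gave 15, 6 higher and 0 lower. Control lung numbers did not pair: same-number correlations were 0.0683 to 0.291 with resolving lung and -0.0638 to 0.0770 with spleen, and not every array correlated best with its own number. The block over the 6 arrays of injured mice, with fewer degrees of freedom, gave 175 for lung against spleen and changed no list's call. At an unadjusted p under 0.05 it gave 3777 genes, against 3944 without the block. With an estimated correlation 0, 0 and 0 lists were called (0, 8 and 4 at an unadjusted p under 0.05), and with fry 0, 10 and 10 (8, 15 and 14). Without the arrays low in Xist the counts were 9, 527, 5 higher and 0 lower, and with the covariate 0 lower. Leaving out each array in turn gave 4 to 212, 508 to 1131 and 681 to 1793 genes, 14 to 21, 16 to 20 and 14 to 18 lists, 1 to 44 higher and 0 to 44 lower; a group then had 2 arrays and shared the spread of the others.

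The results of named genes that changed direction were called neither before nor after. For resolving against control lung, Areg moved from 0.15 to -0.139 without the arrays low in Xist and -0.0303 with the covariate (range without 1 array -0.139 to 0.416). Without the arrays low in Xist, Xist was at 0.333 (-3.01 to 0.333), Eif2s3y at -0.0513 (-0.0513 to 0.561), Col1a1 at -0.0426 (-0.0426 to 1.84), Col1a2 at -0.0654 (-0.0654 to 1.32), Col3a1 at -0.230 (-0.230 to 1.64) and Kdm5d at -0.166 (-0.166 to 0.527), Kdm5d also at -0.0908 with the covariate and -0.0569 with array weights. Mcpt8 ranged over -0.265 to 0.0615 and Ms4a2 over -0.0435 to 0.200. For resolving lung against spleen, Cpa3 was at 0.0829 without the arrays low in Xist (-0.597 to 0.0279) and Uty at -0.0874 with array weights and -0.224 with the covariate (-0.256 to 0.254), and Kdm5d ranged over -0.610 to 0.00115 and Xist over -2.01 to 2.41. For control lung against spleen, Foxp3 ranged over -0.0357 to 0.00707. Quantile normalisation applied again, the floor, trend and robust moderation and the mean of a gene's rows moved no count by over 1.5 times. Signal over background limits dim markers: 5 of 21 epithelial, 8 of 25 macrophage and 0 of 18 fibroblast genes lay above the dim level in all arrays.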

Other observations

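The lists described here were fixed before the data were examined, and which of them to describe, and the clock genes, were chosen after the result was seen.

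In control lung against resolving spleen, where organ and injury differ together, NF-kB genes were shifted up (median 0.24, camera adjusted p = 0.00368, adjusted p = 0.459 with an estimated correlation), with 7 of 22 members higher and 1 lower over all genes and 11 and 2 adjusted over the list alone. Tnfaip3, an inhibitor of the pathway, was at 2.07, SE 0.26, the apoptosis inhibitor Birc3 at 0.76, SE 0.07 and Nfkbiz, a nuclear regulator, at 0.87, SE 0.12, while the lymphotoxin gene Ltb was lower (-0.73, SE 0.10). Cholesterol synthesis genes were shifted down (median -0.08, camera adjusted p = 0.0296, adjusted p = 0.467 with an estimated correlation). Over all genes 4 of 21 were lower (2 higher and 8 lower adjusted over the list alone), among them the sterol enzymes Fdft1 (-0.42) and Dhcr7 (-0.50). Interferon-stimulated genes were shifted down (median -0.16, camera adjusted p = 9.00e-04, adjusted p = 0.173 with an estimated correlation), with Ifit2 (-0.83), Parp14 (-0.37) and Ifih1 (-0.44) lower over all genes and 9 adjusted over the list alone. Genes of CD8 T or NK cells were shifted up (median 0.20, camera adjusted p = 0.0290, adjusted p = 0.260 with an estimated correlation), with granzyme A, Gzma (1.32, SE 0.18), and the death ligand Fasl (0.49, SE 0.11) higher over all genes and adjusted over the list alone. The camera adjusted p of the CD8 T or NK cell list was 0.0800, 0.0625 and 0.0578 without control lung replicate 2, spleen replicate 1 and spleen replicate 3. For cholesterol synthesis it was 0.0617 without spleen replicate 2. The median was -0.12 for cholesterol synthesis without control lung replicate 3. It was 0.33 for the CD8 T or NK cell list without spleen replicate 2.

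Chemokine and homing receptors were shifted up in control lung (median 0.42, camera adjusted p = 0.00104, adjusted p = 0.227 with an estimated correlation), with 4 members higher and 1 lower over all genes and 9 and 1 adjusted over the list alone. Ccr2, a receptor for inflammatory chemokines, was at 1.31, SE 0.11 and Cxcr4 at 1.78, SE 0.17, while Cxcr5, which guides cells to B cell follicles, was lower (-1.29, SE 0.21). The helper lineage (median 0.21, camera adjusted p = 0.00175), chemokine (median 0.38, camera adjusted p = 0.0113), epithelium (median 0.96, camera adjusted p = 7.59e-13), endothelium (median 0.52, camera adjusted p = 0.00192) and fibroblast lists (median 0.51, camera adjusted p = 0.0351) were shifted up, and the B cell (median -0.70, camera adjusted p = 2.64e-07) and erythroid and platelet lists (median -2.63, camera adjusted p = 2.73e-05) down. In control lung replicates 1, 2 and 3 the list mean was 4.34, 2.86 and 2.72 for endothelium, 4.04, 2.62 and 2.58 for fibroblasts, 6.09, 5.15 and 5.06 for epithelium and 4.23, 3.65 and 3.68 for chemokines. In the spleen arrays it was 2.57, 2.61 and 2.63 for endothelium, 2.37, 2.36 and 2.46 for fibroblasts, 3.06, 3.39 and 3.51 for epithelium and 3.35, 3.34 and 3.13 for chemokines. With an estimated correlation the adjusted p of the helper lineage, chemokine, epithelium, endothelium, fibroblast, B cell and erythroid lists was 0.260, 0.765, 0.260, 0.765, 0.765, 0.410 and 0.260. In that order 5, 2, 9, 1 and 0 members were higher and 3 and 4 lower over all genes, and 8, 3, 12, 1, 0, 10 and 7 adjusted over the list alone, with 1 helper lineage gene lower. The T cell identity (median -0.03, mean 0.01, camera direction down, adjusted p = 0.676), dendritic cell (median 0.01, mean -0.11, camera direction down, adjusted p = 0.802) and sex-linked lists (median -0.23, mean 0.27, camera direction down, adjusted p = 0.878) and the other 11 lists did not shift. The camera adjusted p of the fibroblast list was 0.508, 0.0697 and 0.0677 without control lung replicate 1, spleen replicate 1 and spleen replicate 2. For endothelium and chemokines it was 0.251 and 0.129 without control lung replicate 1. With 1 array left out, the neutrophil list was called with 0.0158 down without control lung replicate 1, the growth factor list with 0.0465 up without control lung replicate 3 and oxidative phosphorylation with 0.0441 down and 0.0481 down without control lung replicate 3 and resolving lung replicate 1. The median was 0.11 for chemokines, 0.053 for endothelium and 0.094 for fibroblasts without control lung replicate 1. It was -0.42 for B cells without spleen replicate 2.

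In resolving against control lung the clock gene Per1 fell (-0.84, SE 0.12, adjusted p = 0.0372 with limma). The clock genes Per2, Cry1, Cry2, Nr1d1, Nr1d2, Dbp, Arntl and Clock did not pass (smallest adjusted p = 0.346, for Nr1d2 at -0.33, SE 0.14). Usp2, Irs2 and Sik1 were looked at in the same set. Usp2 and Irs2 fell past the threshold (limma adjusted p = 0.0323 and 0.00967), and Sik1 did not pass (-0.90, SE 0.16, adjusted p = 0.0620). The hours of harvest were not given in the sources used here.

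The first principal component of all genes took 40.3% of the variance and parted spleen (scores of 30.0 to 32.6) from lung (-40.2 to -4.19), and the next took 25.1%, with resolving lung replicate 1 at -39.5 and the other 8 arrays between -13.1 and 22.4.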
